A study of Mus musculus with 6 samples.

How the data were processed

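Gene expression was measured in mouse embryonic fibroblasts, connective-tissue cells grown in culture from embryos, that were wild type for Klf4 (Klf4 +/+) or lacked both working copies of it (Klf4 -/-, called Klf4-null here). There were 6 samples, 3 wild-type and 3 Klf4-null, each measured on 1 array. Per the labels' protocols, total RNA was extracted with Trizol from cells close to confluence, treated with DNase I and cleaned on a column, and biotinylated cRNA was made from it for Illumina bead arrays. The dye field of the labels names both Cy3 and Cy5, but 1 value per sample and probe was deposited, and the arrays were treated as having 1 colour. Per the labels, all samples were of the C57Bl/6 strain with an age of 13 days. The labels number the replicates but name no separate cultures or embryos, so the p-values measure only the spread between these samples, which may be technical.

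The deposited table gave 1 intensity per probe and array for 46621 probes. These intensities are linear and all positive, with medians of 51.7 to 51.8 on the 6 arrays, and their sorted values were nearly the same on every array, so the authors' deposited intensities had been normalized between arrays. Whether background had been subtracted is unknown, although a lowest value of 25.8 on each array shows no probe near 0. The scanner software, the normalization method and the annotation build were not given in the sources used here. A further deposited table held 12 columns of signals and detection p-values whose names match no sample's labels. Those columns were not used, and only its pairing of probes with gene symbols was taken.

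Before the data were examined, the plan had been to correct background with normexp from the control signals, to normalize by quantiles, and to filter probes on the detection p-value. With the unmatched columns set aside, neither that correction nor that filter could be run, so log2 of the deposited values, listed beforehand as a second choice, became the values tested. Quantile normalization was not repeated on them, as they had been normalized, and was run only in alternatives. The filter was replaced by a background floor that was chosen after the data were examined and after a first fit with a fixed floor at an intensity of 64 had been seen. On each array the mode of the log2 values was taken as background, the spread of values below the mode was mirrored, and the floor was set at the 95th percentile of that distribution. The floors lay at intensities of 54.0 to 54.2, and 21044 to 21234 probes per array were above them. A probe was tested if it was above the floor on at least 3 of the 6 arrays, which kept 21823 probes. Where a probe was above the floor on no array of a group, its level there has only an upper bound, and the ratio is given as at least N-fold, computed from the mean log2 value of the brighter group and the higher of floor and signal on each array of the dimmer group. If the deposited values still hold background, ratios of dim probes understate the change.

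Probe symbols were updated through RefSeq gene names (assembly GRCm38.p6), which were used for names only. The symbol was a current one for 25438 probes and a unique synonym of a current one for 8747 probes, and the deposited symbol was kept for 12436 probes. Genes of near-identical families, such as the Prl2c genes, may share probe signal and are named as uncertain. Where counts are of genes, each gene was represented by its probe with the highest mean over all 6 arrays, which gave 16212 genes.

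The 1 comparison of the design, Klf4-null against wild type, was fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 on all 6 arrays without covariates, with 2-sided p-values and Benjamini-Hochberg adjustment. A probe was called changed at an adjusted p under 0.05. Log2 fold changes are Klf4-null minus wild type, with their standard error (SE). Adjusted p-values of single genes are those over all probes tested, and counts of list members use the adjustment over all genes tested unless it is said to be over the list alone. The procedure was tested on simulated data made for 21823 probes with the real means and spreads. It recovered 100% of the probes lowered and 96% of those raised by a log2 fold change of 1 in size. It recovered 48% and 56% of those lowered and raised by 0.5, and 2.6% of its calls were false. The simulation left 21623 of its probes unchanged, whereas 8483 of 21823 probes changed in the real data. Since the adjusted threshold depends on that share, these results do not carry over to the real comparison. Permutation tests (100000 permutations) and Fisher's exact test were 2-sided. The number of arrays limits the precision.

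Named genes follow a rule fixed before the data were examined. It takes Klf4, the 12 higher and 12 lower genes with the largest changes whose groups do not overlap, without symbols that are clone or accession-like names in the deposited table or after updating, up to 4 members of each list with the largest changes, and 5 sex-linked genes. Genes outside it are said to have been chosen after their values were seen. The 32 gene lists were also fixed before the data were examined. They cover G1/S and DNA replication, G2/M and mitosis, G1 cyclins and their regulators, p53 targets, DNA repair, Kruppel-like and Sp factors, pluripotency, immediate early genes, collagens and matrix, matrix proteases and inhibitors, smooth muscle and contractile cytoskeleton, adhesion, TGF-beta targets, the Wnt pathway, growth factors, interferon response, cytokines and chemokines, cholesterol synthesis, glycolysis and hypoxia, Nrf2 and glutathione, the unfolded protein and heat shock response, imprinted genes, Hox genes, ribosomal proteins, sex-linked genes, and markers of epithelial, endothelial, macrophage and blood, neural and glial, skeletal muscle, cartilage and bone, and adipocyte cells. The 30 lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists.

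The alternatives were quantile normalization after an offset of 16, no filter on dim probes, probes above the floor on all 6 arrays, a floor at the 99th percentile, the replicate number as a block, trend and robust variance, array weights, a Welch test per probe, which estimates the variance of each probe on its own, limma's treat against 1.5-fold, the mean of a gene's probes, camera with an estimated correlation, fry, and leaving out each array in turn. Added after the data were examined were normexp correction with offsets of 16 and 50, the floor at 64, and a fit without genes whose changed probes disagree in sign. Figures were drawn with matplotlib 3.10.9.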

Results

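The transcriptomes of 3 wild-type and 3 Klf4-null samples of mouse embryonic fibroblasts were compared on Illumina bead arrays. Klf4 encodes a zinc-finger transcription factor of the Kruppel-like family, and the title of the series links its disruption to proliferation and to the formation of tumours. The question addressed by the comparison was which transcripts differ when the gene is disrupted. Values are normalized probe intensities with no count behind them, and 21823 of 46621 probes lay above the estimated background on at least 3 of the 6 arrays.

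Klf4 itself was read by 3 probes, and they did not move together. Probe ILMN_1241903 had an intensity of 98.7, 95.6 and 103 on the wild-type arrays (mean 99.04 ± 3.61, SD, n = 3) and of 39.7, 46.8 and 43.7 on the null arrays (43.4 ± 3.55), where it was not above background. It fell at least 1.83-fold (log2 fold change -1.19, SE 0.08, adjusted p = 5.3e-08 by limma). Probe ILMN_1221264 fell at least 1.27-fold, from 69.1 ± 7.82 to 43.5 ± 2.05, again to background on every null array (log2 fold change -0.66, SE 0.09, adjusted p = 4.8e-05). The brightest Klf4 probe, ILMN_2593684, rose from 426 ± 60.03 to 715 ± 19.2 (log2 fold change 0.76, SE 0.10, adjusted p = 2.4e-05). The per-array values of this probe were 403, 494 and 380 in wild type and 702, 707 and 737 in null cells. The positions of the probes relative to the disrupted part of the gene were not given in the sources used here, and a probe outside that part does not test the labels. The rise of the brightest probe did not pass a test that estimates the variance of each probe on its own or a test against 1.5-fold, and the fall of ILMN_1221264 did not pass the latter.

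Sex-linked transcripts also differed between the groups. Xist, the transcript that coats the inactive X chromosome, rose 3.70-fold on 1 of its 2 probes, from 70.2 to 260 (log2 fold change 1.89, SE 0.09, adjusted p = 7.1e-10), and its other probe was at background in both groups. The Y-linked gene Kdm5d fell at least 2.24-fold on 1 of its 2 probes, from 122 to 43.1 (adjusted p = 7.8e-08). Ddx3y and Eif2s3y were at background in both groups, and 1 of the 3 probes of Uty gave 80.1 in wild type and 78.0 in null cells (log2 fold change -0.04, adjusted p = 0.747). Of its other probes, ILMN_2517601 was above background on 2 of 3 wild-type arrays and on no null array, too few arrays to be tested, and ILMN_2467512 was at background in both groups. The list was fixed to read the sex of the cultures, but its probes conflict and do not settle it. A difference in sex between the groups cannot be told apart from an effect of genotype on these transcripts.

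**Figure D1:**
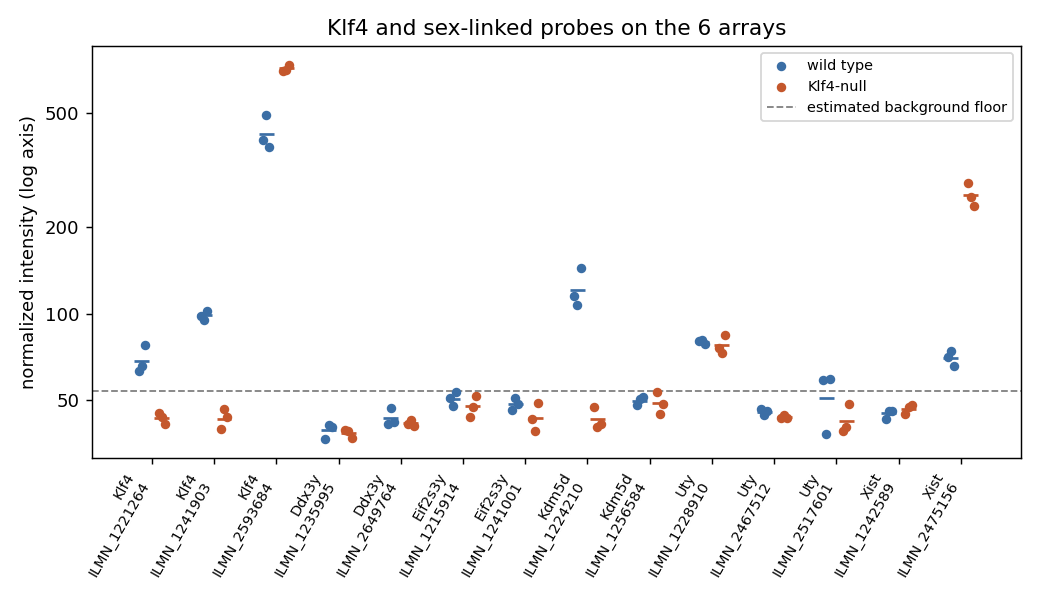
Normalized intensity (log axis) of each Klf4 probe and each probe of 5 sex-linked genes on the 3 wild-type and 3 Klf4-null arrays; dots are arrays, short lines are means of log2 values, and the dashed line is the mean background floor. Probes ILMN_1221264 and ILMN_1241903 of Klf4 are below the floor on every null array, while ILMN_2593684 is at 426 in wild type and 715 in null cells.

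Among the genes with the largest differences, Klf4-null cells had far less Dlk1 and Thy1 and far more Sumo3, Col18a1 and Grem1. Dlk1, an imprinted transmembrane protein that inhibits adipocyte differentiation, fell at least 271-fold, from an intensity of 14710 ± 1082 (SD, n = 3) to 47.8 ± 0.443, which is background (log2 fold change -8.26, SE 0.08, adjusted p = 3.7e-16 by limma). Thy1, a surface glycoprotein of fibroblasts, fell at least 60.9-fold (log2 fold change -6.07, SE 0.08). The other probe of Thy1, too dim to be tested, gave -0.23 (adjusted p = 0.0534 by limma without the filter). Sumo3, a small ubiquitin-like modifier, rose 70.0-fold, from 84.4 ± 4.64 to 5907 ± 300 (log2 fold change 6.13, SE 0.08, adjusted p = 8.4e-15). Col18a1, a basement membrane collagen, rose 51.8-fold (log2 fold change 5.69, SE 0.10). The other probe of Col18a1, too dim to be tested, gave 0.14 (adjusted p = 0.357 by limma without the filter). Grem1, a secreted antagonist of bone morphogenetic proteins, rose at least 34.0-fold (log2 fold change 5.33, SE 0.11).

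The remaining genes among the 12 with the largest rises were Smpdl3b, Mcm6, Gap43, Csrp1, Kif2c, Ccdc3, Blnk, Rab15 and Crtap, with log2 fold changes from 5.03 for Crtap to 5.69 for Smpdl3b. The rule for naming genes leaves out those deposited under clone names, here Sdr39u1, at 5.12 on one probe and 2.23 on the other, which is named after its values were seen, and 2 transcripts that fell, at -5.23 and -4.59. Of these, Smpdl3b, Gap43, Kif2c, Blnk, Rab15 and Crtap were above background on no wild-type array, and Ccdc3 was above it on 2 of 3. Mcm6, a subunit of the replicative helicase, rose 40.4-fold on probe ILMN_1217331, but its brighter probe ILMN_1233857 gave a log2 fold change of 0.18 with an adjusted p of 0.229. The 12 genes with the largest falls also held Ptgis, the prostacyclin synthase, at -5.27, and the imprinted genes Slc38a4 at -5.21 and Grb10 at -4.53 on the log2 scale. Slc38a4 and Bicc1 were above background on 2 of 3 null arrays. Igf2bp3, an RNA-binding protein of embryonic tissues, fell 21.8-fold (log2 fold change -4.45, SE 0.09). Fez1 gave -5.22, Sirpa -4.84 and Hyi -4.51, and Bicc1 gave -5.24 on one probe and -0.12 (adjusted p = 0.442) on the other. Prl2c2 and Prl2c3 fell 46.9-fold and 42.1-fold, but members of this placental prolactin family are nearly identical in sequence, so which of them fell is uncertain.

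**Figure D2:**
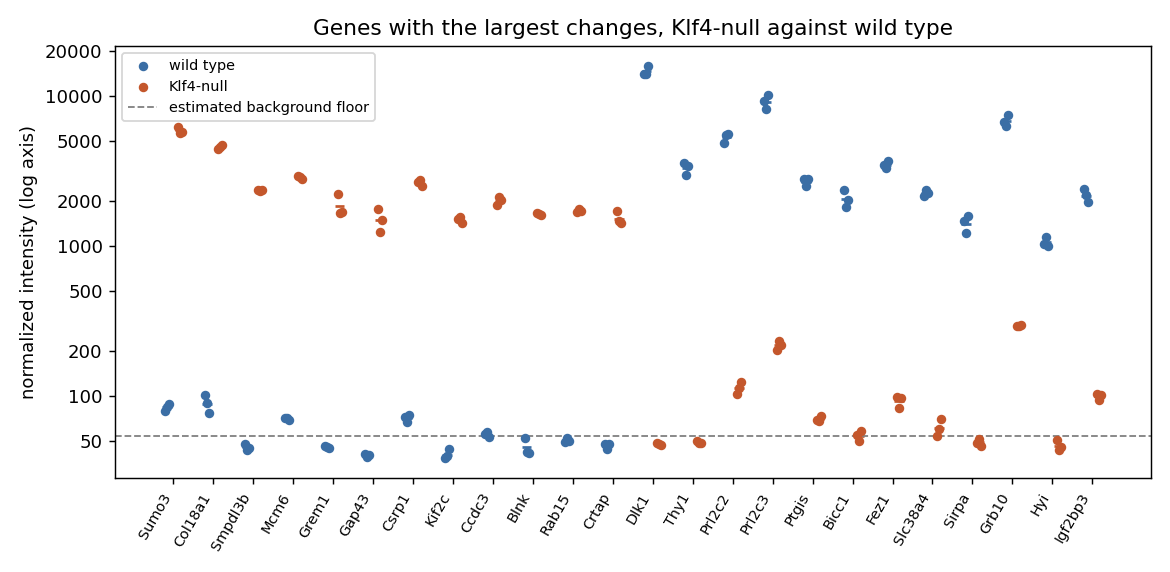
Normalized intensity (log axis) of the 12 genes with the largest rises and the 12 with the largest falls, clone names left out, on the 3 wild-type and 3 Klf4-null arrays; dots are arrays, short lines are means of log2 values, and the dashed line is the mean background floor. Dlk1 goes from 14710 in wild type to 47.8 in null cells, and Sumo3 from 84.4 to 5907.

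Over all probes tested, 8483 changed (38.9%), of which 4141 were higher and 4342 lower in null cells, and 9789 had an unadjusted p under 0.05. Changes of at least 2-fold numbered 764 higher and 631 lower probes, 1395 in all, and 912 among probes above background on all 6 arrays. Of genes, 6467 of 16212 changed, 3126 higher and 3341 lower, and 627 and 530 did so by at least 2-fold. The 3 null arrays did not overlap the 3 wild-type arrays for 10315 probes (47.3%). Chance gives 10%, but only if the arrays of a group are independent samples. As the labels name no separate cultures or embryos, these counts cannot tell an effect of genotype from a difference between cultures. The correlation of arrays across the tested probes was 0.995 to 0.996 within wild type, 0.996 to 0.998 within null cells and 0.947 to 0.951 between the groups. Of 1211 genes with 2 or more changed probes, 130 (10.7%) had probes that moved in opposite directions. Besides Mcm6, Bicc1, Rbl1 and Kif23, the changed genes Cdc25c, Ccnd2, Cdkn2c, Xrcc2, Egr3, Smtn, Id2, Tcf7, Irf1, Slc7a11, Gstm1, Hspa1b, Hoxc6 and Egfl7, described below by 1 probe each, had a further tested probe that did not pass. Some other named genes had further probes that passed in the same direction with much smaller log2 fold changes. Examples are Fbln1 (2.33, with 0.52 and 0.41 on others), Mmp13 (3.79, with 0.53) and Hyi (-4.51, with -0.67). Counts fell to 4208 probes with the variance of each probe estimated on its own and to 1766 with a test against 1.5-fold.

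Genes of proliferation, the topic of the series title, moved in both directions. Of 32 tested G1/S and DNA replication genes, 10 rose, 6 fell and 16 did not pass, with 17 passing when adjusted over the list alone. The flap endonuclease Fen1 rose 1.51-fold (log2 fold change 0.60, SE 0.09, n = 3 per group) and the transcription factor E2f1 rose 1.46-fold (0.54, SE 0.09), while cyclin E1 (Ccne1) fell 2.15-fold (log2 fold change -1.10, SE 0.10) and the clamp loader subunit Rfc3 fell 1.70-fold. Of 33 G2/M and mitosis genes, 9 rose, 3 fell and 21 did not pass, with 12 passing when adjusted over the list alone. The mitotic kinesin Kif2c rose at least 27.7-fold (log2 fold change 5.20, SE 0.08), Kif23 rose 2.59-fold on its brighter probe (its other probe gave a log2 fold change of 0.04, adjusted p = 0.804) and the proliferation marker Mki67 rose 1.36-fold, while the phosphatase Cdc25c fell 1.42-fold. The list's mean log2 fold change of 0.27 stood above its median of 0.09. Neither list passed the camera test (adjusted p = 0.388 for G1/S and 0.0971 for G2/M), though G2/M passed without a filter on dim probes.

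Of 15 G1 cyclins, cyclin-dependent kinases and their regulators, 5 rose and 3 fell, 8 also passing when adjusted over the list alone. Cdk2 rose 2.04-fold (log2 fold change 1.03, SE 0.08), cyclin D2 (Ccnd2) fell 1.53-fold on its brightest probe, and the inhibitor Cdkn2c fell 1.45-fold. Rbl1, a pocket protein, gave a log2 fold change of 0.47 on its representing probe and -0.55 on another. The list's mean was 0.07, its median -0.03 and its camera direction up (adjusted p = 0.611). Of 18 p53 targets, 8 rose and 3 fell, 11 also when adjusted over the list alone, led by Gadd45a at 1.92-fold and Plk2 at 1.53-fold (camera adjusted p = 0.0808). Of 25 DNA repair genes, 2 rose, Xrcc6 at 1.59-fold and Xrcc2 at 1.47-fold, and 9 fell, led by Rad51c at 2.04-fold and the damage sensor Xpc at 1.56-fold. All 11 passed when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.249).

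The lists of cytokines and chemokines and of matrix proteases and inhibitors were higher in null cells. Of 18 tested cytokine and chemokine genes, 12 rose, 2 fell and 4 did not pass, 15 passing when adjusted over the list alone, and the list rose (camera adjusted p = 4.9e-05, and adjusted p = 0.19 with an estimated correlation). The chemokine Ccl5 rose at least 10.6-fold (log2 fold change 3.73, SE 0.08, n = 3 per group), complement C3 rose 8.78-fold, Cxcl1 rose 8.48-fold and Cxcl12 rose 6.79-fold. Of 20 matrix proteases and inhibitors, 12 rose and 2 fell, 14 also when adjusted over the list alone (camera adjusted p = 0.00055, and adjusted p = 0.19 with an estimated correlation). The metalloproteinases Mmp3 (at least 26.8-fold), Mmp13 (at least 11.4-fold) and Mmp10 (5.32-fold) rose, while the procollagen peptidase Adamts2 fell 15.95-fold (log2 fold change -4.00, SE 0.09).

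Of 29 collagen and matrix genes, 13 rose, 6 fell and 10 did not pass, 20 passing when adjusted over the list alone (camera adjusted p = 0.0041, and adjusted p = 0.212 with an estimated correlation). The proteoglycan decorin (Dcn) rose 21.5-fold (log2 fold change 4.42, SE 0.08), Col12a1 at least 6.31-fold, Col3a1 5.65-fold and fibulin-1 (Fbln1) at least 4.54-fold. Of 16 smooth muscle and contractile genes, 7 rose and 1 fell, 8 also when adjusted over the list alone (camera adjusted p = 0.012, and adjusted p = 0.19 with an estimated correlation). Csrp1 rose 36.9-fold, tropomyosin Tpm1 8.55-fold and smoothelin (Smtn) 1.87-fold, while the smooth muscle actin Actg2 fell 3.45-fold.

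The list of TGF-beta targets rose, with 9 of 14 members higher and 3 lower and 13 passing when adjusted over the list alone (camera adjusted p = 0.024, and adjusted p = 0.19 with an estimated correlation). The matrix protein Tgfbi rose at least 19.9-fold (log2 fold change 4.45, SE 0.08) and Pmepa1 3.69-fold, while the inhibitors of differentiation Id3 and Id2, which also respond to bone morphogenetic proteins, fell 5.91-fold and 3.00-fold. This list did not pass over probes above background on all 6 arrays. Of 13 genes of the Wnt pathway, 8 rose and 2 fell, 10 also when adjusted over the list alone (camera adjusted p = 0.0096, and adjusted p = 0.19 with an estimated correlation). The feedback inhibitor Axin2 rose at least 2.54-fold (log2 fold change 1.57, SE 0.08), Dkk3 2.20-fold, the receptor Fzd7 2.00-fold and the transcription factor Tcf7 at least 1.62-fold.

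The lists of interferon response, unfolded protein response and immediate early genes rose too. Of 20 interferon response genes, 13 rose and 2 fell, 15 also when adjusted over the list alone (camera adjusted p = 0.0087, and adjusted p = 0.315 with an estimated correlation). Cxcl10 rose at least 2.08-fold, the transcription factor Irf1 1.91-fold and the GTPase Irgm1 1.74-fold, while the immunoproteasome subunit Psmb9 fell at least 2.22-fold. Of 18 genes of the unfolded protein and heat shock response, 9 rose and 3 fell, 12 also when adjusted over the list alone (camera adjusted p = 0.024, and adjusted p = 0.19 with an estimated correlation). Chac1 rose 3.92-fold (log2 fold change 1.97, SE 0.09), Hspa1b 2.07-fold and Ddit3 2.07-fold, and Herpud1 1.92-fold. Of 15 immediate early genes, 9 rose and 3 fell, 12 also when adjusted over the list alone (camera adjusted p = 0.033, and adjusted p = 0.199 with an estimated correlation). The phosphatase Dusp1 rose 2.50-fold, Ier3 1.97-fold and Atf3 at least 1.39-fold, while Egr3 fell 2.01-fold.

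**Figure D3:**
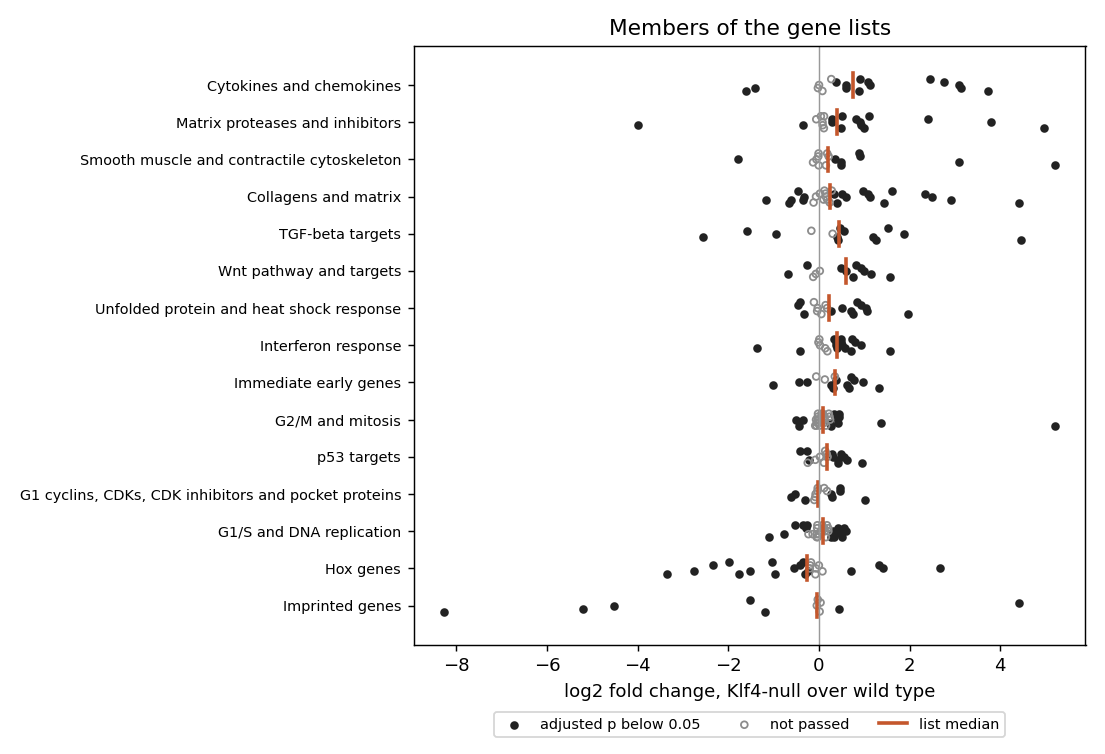
Log2 fold change (Klf4-null over wild type) of each tested member of 15 gene lists, the 11 that passed camera at the preset correlation and 4 lists of growth control; filled dots are genes with an adjusted p below 0.05, open dots are genes that did not pass, and bars are list medians. The Hox list lies lower, with a median of -0.27, and the cytokine list higher, with a median of 0.75. The imprinted list has a median of -0.05 and a mean of -1.44.

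The Hox genes, which specify position along the body axis, fell as a group. Of 24 tested, 13 fell, 4 rose and 7 did not pass, 18 passing when adjusted over the list alone (camera adjusted p = 0.011, and adjusted p = 0.19 with an estimated correlation). Hoxc6 fell 10.2-fold (log2 fold change -3.35, SE 0.10, n = 3 per group) on its brighter probe, Hoxd4 fell 6.78-fold and Hoxb5 at least 4.52-fold, while Hoxd10 rose at least 4.86-fold (log2 fold change 2.67, SE 0.08). With a cut chosen after the values were seen, 13 of the 17 tested genes in paralog groups 1 to 8 fell and 0 rose. Of the 7 in groups 9 to 13, 4 rose and 0 fell. The rises in the latter set were those of Hoxa9, Hoxd10, Hoxa11 and Hoxd13. Imprinted genes fell as a list, with 5 of 11 lower and 2 higher, 7 also when adjusted over the list alone (camera adjusted p = 0.035, and adjusted p = 0.199 with an estimated correlation). Its mean log2 fold change was -1.44 and its median -0.05, as Dlk1, Slc38a4 and Grb10 fell and Dcn rose. The call was lost without the filter on dim probes, over probes above background on all 6 arrays, with quantile normalization after an offset of 16, and with normexp correction at an offset of 50 followed by quantile normalization.

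**Figure D4:**
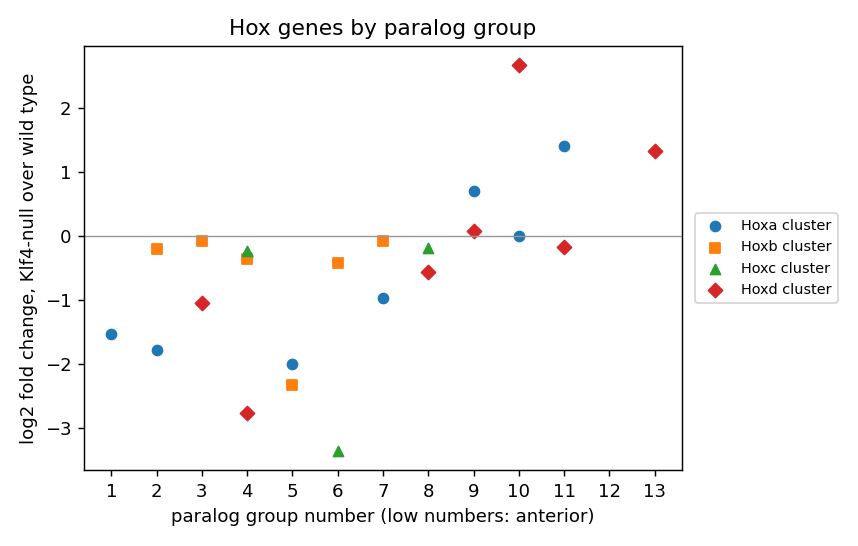
Log2 fold change (Klf4-null over wild type) of 24 Hox genes against their paralog group number, with symbols for the 4 clusters. Genes of groups 1 to 8 lie below 0, down to -3.35 for Hoxc6, and the highest value is 2.67 for Hoxd10.

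The other lists did not pass the camera test. Of 17 adhesion genes, 9 rose and 4 fell, 14 passing when adjusted over the list alone. Besides Thy1, Alcam fell 5.15-fold, while Cdh13 rose at least 5.03-fold and the integrin Itga3 rose 3.97-fold (list mean 0.08, median 0.30, camera direction up, fry direction down, camera adjusted p = 0.0774). Of 23 growth factor genes, 11 rose and 7 fell, 18 also when adjusted over the list alone. The EGF receptor ligand amphiregulin (Areg) rose at least 19.3-fold (log2 fold change 4.42, SE 0.08), Igfbp4 12.7-fold, and the EGF receptor Egfr at least 4.96-fold (camera adjusted p = 0.219). Gas6, a ligand of TAM receptors, rose 8.96-fold and was above background on 1 of 3 wild-type arrays. Of 15 Kruppel-like and Sp factors, each read by its brightest probe, 5 rose and 0 fell, the rises including that of the brightest Klf4 probe, whose other 2 probes fell, with 4 passing when adjusted over the list alone, led by Klf5 at 2.07-fold (log2 fold change 1.05, SE 0.09, camera adjusted p = 0.101).

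In the Nrf2 and glutathione list, 3 of 20 genes rose and 6 fell, 9 also when adjusted over the list alone. The glutathione transferases Gsta4, Gstm2 and Gstm1 fell 9.36-fold, 4.91-fold and 2.54-fold, and the cystine transporter Slc7a11 rose 2.98-fold (camera adjusted p = 0.315). Of 21 glycolysis and hypoxia genes, 6 rose and 9 fell, 16 passing when adjusted over the list alone, with Ndrg1 up 2.78-fold, Adm up 2.73-fold and P4ha2 down 1.98-fold (list mean 0.04, median -0.06, camera direction down, fry direction up, adjusted p = 0.965). Of 21 cholesterol genes, 5 rose and 5 fell, 10 also when adjusted over the list alone, with Nsdhl down 2.12-fold and Mvk up 2.01-fold (list mean -0.03, median 0.05, camera direction up, fry direction down, adjusted p = 0.985). Of 16 ribosomal protein genes, 6 fell and 0 rose, 6 also when adjusted over the list alone, led by Rpl22 at 1.64-fold (camera adjusted p = 0.0975). Of 7 pluripotency genes, Dppa4 rose at least 1.52-fold, and Sox2, above background on 2 of 3 wild-type arrays, rose 1.33-fold, and both passed when adjusted over the list alone (camera adjusted p = 0.422).

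Markers of other cell types that an embryo-derived culture could hold did not move together. In the neural and glial list, Gap43 rose at least 27.5-fold and nestin (Nes) at least 14.96-fold (log2 fold change 4.21, SE 0.08). The other probe of Nes, too dim to be tested, gave 0.03 (adjusted p = 0.892 by limma without the filter). Mbp, Tubb3 and Gfap gave -0.20, -0.17 and -0.11 and did not pass over all genes. Adjusted over the list alone, 4 of the list's 5 genes passed (mean 1.79, median -0.11, camera direction up, adjusted p = 0.146). In the epithelial list, Krt14 fell at least 2.63-fold, Krt7 fell 1.39-fold (above background on 1 of 3 null arrays) and Pkp1 rose at least 1.99-fold among 7 genes, 3 also when adjusted over the list alone (adjusted p = 0.662). Of 10 endothelial markers, Ramp2 and Eng rose 1.81-fold and 1.57-fold and Egfl7 and Cdh5 fell 1.98-fold and 1.20-fold, the call for Cdh5 being lost when either of 2 arrays was left out, 4 also when adjusted over the list alone (mean 0.02, median -0.04, camera direction up, fry direction down, adjusted p = 0.965).

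Of 5 macrophage and blood markers, Cd14 rose 2.68-fold and Hba-a1 and Coro1a fell 1.26-fold each, Coro1a being above background on 1 of 3 null arrays, 3 also when adjusted over the list alone (mean 0.16, median -0.07, camera direction up, adjusted p = 0.965). Of 12 skeletal muscle markers, Tnnc1 rose 3.07-fold and Chrna1, above background on 1 of 3 wild-type arrays, 1.91-fold, and Tnnt2 and Acta1 fell 1.97-fold and 1.85-fold, with 5 passing when adjusted over the list alone (mean 0.02, median -0.03, camera direction down, fry direction up, adjusted p = 0.965). Of 8 cartilage and bone markers, Sox9, a transcription factor of chondrocytes, fell 5.48-fold (log2 fold change -2.45, SE 0.09), Mgp fell 1.19-fold (a call lost when any of 5 arrays was left out) and Spp1 rose 1.47-fold, 3 also when adjusted over the list alone (adjusted p = 0.76). Of 2 tested adipocyte markers, lipoprotein lipase (Lpl) fell at least 6.90-fold and adiponectin (Adipoq) did not pass at -0.10. This list and the sex-linked list, in which 2 of 3 tested genes changed (mean 0.12, median -0.04), had too few members for the test.

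Of the 30 lists tested, 11 passed with the preset correlation and 0 with an estimated correlation. Of these 11, the estimate lay above the preset 0.01 only for interferon response (0.212), collagens and matrix (0.067) and cytokines and chemokines (0.046). For the others it lay below, as at -0.027 for matrix proteases and inhibitors and -0.029 for Hox genes. A higher correlation therefore does not account for the loss of those calls. With an estimated correlation camera also takes its degrees of freedom from the 6 arrays, and with a preset one from the genes tested. The fewer degrees of freedom raise the p-values on their own. For matrix proteases and inhibitors the camera p before adjustment went from 3.7e-05 to 0.0108, although the estimated correlation was lower. The fry test, which asks whether a list's genes move on balance one way without comparing them with other genes, called 25 lists, and its mixed version called 30.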

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

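The alternatives added after the data were examined were the normexp corrections, the floor at an intensity of 64 and the fit without genes whose changed probes disagree in sign; the others were planned, apart from the floor itself. No called result reversed its direction in any alternative in which it was tested. The mean of a gene's probes was used for lists only, not for single genes such as Klf4. Setting aside the Welch test and the test against 1.5-fold, the number of changed probes was 6963 to 9068 over 11 alternatives, and the floor at 64 gave 3868 higher and 4139 lower of 16738 probes. The Welch test gave 4208 changed probes (2160 higher, 2048 lower) and left the Klf4 level of 0.76 on the brightest probe with an adjusted p of 0.0753. The test against 1.5-fold gave 1766 (955 higher, 811 lower), as its construction asks for a larger change, and neither the Klf4 level of 0.76 nor that of -0.66 on ILMN_1221264 passed it. Probes changed by at least 2-fold were 912 among those above background on all 6 arrays, a filter that removes genes dark in either group.

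Camera with an estimated correlation called 0 lists, fry 25 and its mixed version 30. With the estimated correlation the adjusted p was 0.19 for the lists of cytokines and chemokines, matrix proteases and inhibitors, Hox genes, smooth muscle, TGF-beta targets, Wnt pathway and unfolded protein response, 0.199 for immediate early and for imprinted genes, 0.212 for collagens and matrix and 0.315 for interferon response. G1/S and DNA replication passed with fry (adjusted p = 0.0257, mixed 2.8e-05), with a range over its alternatives of 2.8e-05 to 0.448. G2/M and mitosis passed with no filter on dim probes (0.033) and with fry (5.8e-05, mixed 9.2e-07), within 9.2e-07 to 0.212. Imprinted genes did not pass with log2(value + 16) and quantile normalization together (0.0533), with normexp at an offset of 50 and quantile normalization (0.0545), with no filter (0.186) or above background on all 6 arrays (0.838), within 1.6e-07 to 0.838, and TGF-beta targets not in the last of these (0.112), within 2.1e-06 to 0.19. The loss of calls with the estimated correlation goes with the fewer degrees of freedom described above. For the other changes the cause was not tested.

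Leaving out each array in turn gave 7174 to 8248 changed probes and 11 to 12 passing lists. Without wild-type replicate 3 the list of Adhesion, cadherins and integrins passed too (adjusted p = 0.0427). The call for Cdh5 ILMN_2771550 was lost without wild-type replicate 1 (adjusted p = 0.0545) and without null replicate 1 (0.0646), and that for Mgp ILMN_2666018 when any 1 array other than wild-type replicate 3 was left out (0.0718 to 0.137). Of the named genes, 63 results lost their call over all alternatives, 36 of these with the test against 1.5-fold and 18 with the Welch test, and 2452 stayed on the same side of the threshold. Results that an alternative could not test are in neither number. Over probes above background on all 6 arrays only 91 could be tested, against 135 with array weights. The deviations of same-numbered arrays from their group means correlated at -0.016, 0.053 and -0.225. These values gave no sign that the replicate number pairs the samples, but they cannot exclude a weak pairing. With the number as a block, 3963 higher and 4088 lower probes were called and 11 lists passed. The neqc settings, the filters on detection p-values, a slide block, and the Welch test for gene lists were planned but not run; the former need columns that match no sample, or slides that the labels do not name. Signal near background limits what can be read, since folds of probes above background on no array of a group are bounds, and those of probes above it on some arrays of a group are ratios that include values at background.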

Other observations

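Several genes outside the fixed lists were among those with large changes, and all genes in this paragraph and the next were chosen after their values were seen. Among transcription factors, En1 fell 20.2-fold (log2 fold change -4.34, SE 0.08, n = 3 per group), Ebf3 18.5-fold (above background on 1 of 3 null arrays) and Dlx2 14.96-fold, each with a further probe that fell, while Scx, a transcription factor of tendon cells, rose at least 23.8-fold (log2 fold change 4.90, SE 0.08, adjusted p = 1.4e-14). The secreted signals Bmp4 and Wnt7b rose at least 11.8-fold and 6.54-fold. The other probe of Bmp4, too dim to be tested, gave a log2 fold change of 0.03 (adjusted p = 0.867 by limma without the filter). Crabp2, which binds retinoic acid in the cell, rose at least 23.9-fold.

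Snurf, at an imprinted locus, fell at least 15.3-fold, and its other 3 probes fell too. The peptide transporter Tap2 and the thrombin receptor thrombomodulin (Thbd) fell at least 9.25-fold and 8.51-fold. The lysophospholipase Enpp2 rose at least 9.92-fold and the cytokine receptor subunit Il6st rose 8.20-fold. Their other probes, too dim to be tested, gave log2 fold changes of -0.02 and -0.06 (adjusted p = 0.922 and 0.785 by limma without the filter).

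The tests below were all chosen after the results they bear on had been seen. Of the 10 ways to split the 6 arrays into 3 and 3, 1, the real one, gave 8483 changed probes, and the highest of the others gave 0. With 10 splits the share cannot go below 0.1, which is too few for a share under 0.05. The other splits also mix the genotypes, so the difference between the groups enters their residual spread and keeps their counts low. The contrast with the real split therefore decides nothing.

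Some probes with changes of at least 8-fold stood beside another probe of the same gene that did not follow them. Among 151 such genes, 75 had another probe on the array, and of these 127 other probes, taken at any brightness, 103 had a log2 fold change of the same sign, or 81.1% (exact 95% confidence interval 73.2 to 87.5), where chance gives 50%, and 76 of the 103 passed the threshold, as did 4 of the opposite sign. The test treats the 127 probes as independent although several share a gene, so the interval is likely too narrow. This test replaced one by another measure, the share of 57 probes bright in either group that passed in the same direction (78.9%), where the change itself helps to decide which probes are bright. A single probe misreading its target could therefore account for some of these changes, and the interval leaves open how many. In 6 genes (Mcm6, Bicc1, Nme7, Rbbp4, Ptgs1 and Ybx3) a probe with an intensity of at least 128 in either group did not follow, for which a change of transcript form may account instead, and without probe positions it cannot be told apart from a probe effect.

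Most tested Hox genes of low paralog number fell and some of high number rose. Over the 24 tested genes the log2 fold change rose with paralog number (Spearman rho 0.625, Pearson r 0.592, permutation p = 0.00113, across genes, which are not independent replicates). Falls and rises were split between groups 1 to 8 and 9 to 13 (Fisher's exact test, p = 0.00042). That cut lies where the signs change in these data, so its p-value is no separate support. As a hypothesis, the wild-type and null cells may come from different body levels of the embryos, though the trend with paralog number restates the pattern in which it was noticed. Signals near background stay open as well. The brighter 12 genes, by the mean over all 6 arrays, gave a rho of 0.384 (permutation p = 0.217). This test replaced a first version on the 15 genes above background on all 6 arrays (0.231, permutation p = 0.4). The first version decides nothing because it drops the genes that fell to or rose from background. A split by the mean also ranks genes dark in either group lower, so the test on 12 genes does not decide the question either. An effect of Klf4 loss itself cannot be told apart from a difference between the cultures, because the labels name no separate embryos and the median SD within a group of 0.0898 measures only the spread of these arrays.

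The Klf4 probes disagreed. ILMN_1241903 and ILMN_1221264, above background on the arrays labelled wild type only, gave log2 fold changes of -1.19 (SE 0.08) and -0.66 (SE 0.09), while the brightest probe gave 0.76 (SE 0.10). As the positions of the probes are not known, an exchange of the wild-type and null labels cannot be told apart from the labels as given by these probes. The rise of the brightest probe may come from a transcript left by the disrupted allele, which cannot be told apart from a probe that reads another transcript.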
